A study of Ericerus pela with 8 samples.

How the data were processed

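RNA was measured by sequencing in 8 libraries from female and male larvae at the first and second instar, female adults at 3 stages and male adults. Per the labels' protocols, insects were washed and homogenised, total RNA was extracted with TRIzol and libraries were made with standard Illumina reagents. The deposited tables give 1 library each. Per the file headers, the authors assigned reads uniquely to assembled unigenes and give the count of such reads per unigene, a whole number of at least 1, with the total in the header. Unigenes with no read are not listed and were taken as 0. Per the file headers, the authors also give RPKM, the percent of each unigene's length covered by reads, its length in bases, gene ontology terms and the best protein match. The deposited RPKM gave back the header totals when recomputed from count and length. The RPKM and coverage columns were used only to check the counts. The aligner, assembler, read filters, strand setting and protein database release are not given in the sources used here, and no genome was used, so no coordinates are given. Counting did not show whether reads of near-identical family members were split or dropped.

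Counts were joined by unigene identifier, which all files share: 147509 unigenes were read in at least 1 library and 56366 in all 8. The median unigene length was 241 bases. A protein match was given for 29028 unigenes (19.7%) and a named protein for 17106. Matched unigenes held 48.9% to 58.5% of the reads of a library. Of the matches, 39.0% were to other arthropods, 24.4% to Hymenoptera, 23.8% to Hemiptera, the order of scale insects, 10.5% to other animals and 1.82% to protists. No best match named a plant, fungus or bacterium, so the matches say nothing about reads of such organisms. Totals ranged from 1460674 to 2303199 reads, and the largest was 1.58 times the smallest. The 10 most abundant unigenes took 0.323% to 1.56% of a library's reads. Levels are CPM, scaled by TMM (edgeR 4.0.16, factors from 0.801 for male adults to 1.07).

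Groups followed the titles, and each held 1 library. The comparisons, the 4-fold rule, the test across stages, the gene lists and the rule for named genes were fixed before the data were examined. Libraries could not be paired beyond their stage because each group held replicate number 1 only. A unigene counted as different between 2 libraries when log2 of the ratio of levels, each with 1 CPM added, was at least 2 in size, with at least 20 reads in either library. For adults each of the 3 female libraries had to pass against the male library in the same direction. Ratios are of levels without the added amount, with an exact conditional binomial interval of 95% that covers counting error only. Against a library at 0 reads the ratio was computed at a floor of 3 reads per library and written as at least that many fold. Sex differences common to the stages were tested with the edgeR quasi-likelihood test (glmQLFit and glmQLFTest) on all 8 libraries with stage as a covariate, filterByExpr, TMM and Benjamini-Hochberg adjustment at 0.05, which left 51155 unigenes and 4 residual degrees of freedom. Its error comes from the departures of stages from a common sex difference and from the spread among the female adult stages, so it is a test across stages. The median biological coefficient of variation was 0.591.

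Gene lists were patterns searched in the match descriptions: wax and long-chain lipid synthesis, cuticle and chitin, egg and yolk, sperm and axoneme, muscle, vision, chemosensation, juvenile hormone and ecdysone, digestion and sugar uptake, mitochondrial respiration, cytosolic ribosome, cell cycle and replication, wing patterning, embryonic patterning, sex determination, neural signalling, immunity, heat shock, detoxification, protein folding and secretion, transposable elements, and signs of host plant or of bacteria and fungi. The host plant list matched 0 unigenes and the bacteria and fungi list 1, an endonuclease III-like protein of animal match at 195 and 161 reads in the first-instar libraries (Unigene121014_FOB), which left 21 lists. For a pair of libraries a list's median log2 ratio was placed as a percentile among 10000 random lists of matched unigenes of the same size, drawn within 20 bins of mean level, as a description of these libraries. In the test across stages, lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation, and with fry. The searched words also take in some other proteins, such as spermidine enzymes under sperm, retinoblastoma proteins under vision and bicaudal under both egg and embryonic patterning. Named genes were fixed by rule: in each sex comparison the 10 highest and 10 lowest ratios among unigenes past the rule with a named protein, 1 per description, in each developmental step the 3 highest and 3 lowest, in the test across stages the 10 lowest adjusted p per direction, and for each list in each sex comparison up to 4 members past the rule with the highest mean level, or the most abundant member where none passed. Names are those of the best match and were not checked by phylogeny. Where the best match lay outside the arthropods this is said.

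Alternatives were library totals or DESeq2 size factors as scaling, added amounts of 0.1 or 5 CPM, a minimum of 100 reads or of 1 read, thinning all libraries to the smallest total, and a counting interval that excludes 1. For the test across stages they were DESeq2 1.42.0, limma-trend, limma-voom, other scaling, no filter, no stage term, summed female adults, thinned counts and each library left out. Counts without unigenes matched outside the arthropods, and adult counts without each female adult library, were added after the data were seen. The ratio steps were tested on first-instar counts simulated with counting error alone, so false calls from spread between replicate libraries were not assessed. Of 8-fold and 16-fold changes 100% were found, and 2 of 33944 unchanged unigenes were called. The interval held the true ratio in 96.3% of 46391 unigenes, and 7.50% of 40 unchanged lists fell outside the middle 95%. The test across stages was run on simulated counts of 51155 unigenes. At a coefficient of variation of 0.6 it found 14.0%, 62.0%, 98.0% and 100% of 4-, 8-, 16- and 32-fold common changes, with 5 false calls. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and R 4.3.3 were used. Gene ontology was not.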

Results

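Transcript levels were compared between the sexes of Ericerus pela, the Chinese white wax scale. In this insect the adult female is wingless and sessile, the male secretes wax at the second instar, and the adult male is winged. The series held 8 RNA-seq libraries, 1 per group: female and male first-instar larvae, female and male second-instar larvae, female adults at an early, a middle and a late stage, and male adults. The libraries differed up to 1.58 times in depth and covered 147509 unigenes, which are assembled transcript fragments. A count of 0 in a library allows a scaled level of up to 1.22 to 2.03 CPM, depending on the library. Because no group had a second library, the differences within a stage had no replicate check, and no p-value is given for them. The intervals are exact 95% intervals for counting error alone. The sample labels do not give the number of insects per library or say whether the sexes came from the same place and host plant, so a sex difference cannot be separated from one between collections. Several unigenes could be pieces of 1 gene, and members of a protein family could share reads, so members of a family are not independent measurements.

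The first comparison asked how female and male first-instar larvae differed. The female library was higher for a serine protease inhibitor-like protein (Unigene117056_FOB, 99 against 0 reads, at least 34.5-fold) and for a putative elongase, an enzyme class that lengthens fatty acids (Unigene152548_FOB, 65 against 0 reads, at least 22.7-fold). The male library was higher for a cathepsin L-like protease, a cysteine protease of lysosomes and guts (Unigene99296_FOB, 678 against 61 reads, 10.6-fold, 8.17 to 14), and for a second cathepsin L-like unigene (Unigene121322_FOB, 7.94-fold, 5.95 to 10.8). It was also higher for LATS1, the kinase of the Hippo growth pathway (Unigene32112_FOB, 175 against 4 reads, 41.8-fold, 16 to 155), and for mitogen-activated protein kinase kinase kinase 15 (Unigene144260_FOB, 65-fold, 11.3 to 2605). Of 36284 unigenes with at least 20 reads in either library, 976 were at least 4-fold higher in the female library and 269 in the male library. Among the 976, 8.40% had a protein match and 40 had a named protein. Among the 269, 39.4% had a match, against 51.7% of the unigenes not 4-fold apart.

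Several unigenes with high female to male ratios matched proteins from outside the arthropods best: heat shock protein 90 (Unigene157445_FOB, 58 against 2 reads, 30.3-fold, 8.03 to 256), an hsp-1 chaperone (Unigene134559_FOB, 31.4-fold, 5.22 to 1280.2) and a 70 kDa heat shock protein (Unigene47793_FOB, 20.9-fold, 3.35 to 867). So did translation initiation factor 5A-1 (Unigene32712_FOB, at least 7.67-fold) and a histidine-rich glycoprotein precursor read in this library alone (Unigene118576_FOB, at least 13.6-fold). NADH dehydrogenase subunit 1, a respiratory chain protein, was at least 11.5-fold higher in the female library (Unigene15511_FOB), and ribosomal protein L3 was 23.0-fold higher at 22 reads against 1 (3.72 to 950, Unigene35653_FOB). A zeta-type 1-acylglycerol-3-phosphate acyltransferase, an enzyme of glycerolipid synthesis, was also higher in females (Unigene138646_FOB, 12.2-fold, 3.85 to 62). On the male side stood 4 further unigenes matched best outside the arthropods: a zinc finger protein (Unigene138890_FOB, at least 25.8-fold), a zinc finger 347-like protein (Unigene152287_FOB, 64.5-fold, 17.5 to 538), a transcription factor YY2-like protein (Unigene132179_FOB, 56.4-fold, 9.74 to 2265) and a kinase of the ASK family (Unigene149053_FOB, 26.3-fold, 9.98 to 98.2). A transposase, also matched outside the arthropods (Unigene135148_FOB, at least 17.2-fold), and a Tigger transposable element-derived protein (Unigene144418_FOB, 85.1-fold, 14.9 to 3398) were higher in males, and both had 1 read or none in each female library. The protein kinase at 92B followed the same direction (Unigene156742_FOB, 25.5-fold, 8.42 to 126).

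The wax and long-chain lipid list had 3 members higher, 5 lower and 68 neither (median log2 ratio -0.48, percentile 0.21). Its members went both ways: an elongase of very long chain fatty acids was higher in females (Unigene146246_FOB, 6.64-fold, 4.55 to 9.96), and a delta-9 desaturase (Unigene83195_FOB, 7.89-fold, 4.32 to 15.8) and a fatty acid synthase (Unigene151582_FOB, 8.99-fold, 3.59 to 29) were higher in males. The cell cycle list had 0 members higher, 0 lower and 88 neither (median log2 ratio -0.54, percentile 0), and with arthropod matches alone a median of -0.39 at percentile 6.3. Its members included MCM7, a replication helicase subunit, at 174 reads in the female and 291 in the male library (Unigene156125_FOB, 1.6-fold, 1.32 to 1.94 in favour of males). The ribosome list had 4 members higher, 0 lower and 46 neither (median log2 ratio 0.41, percentile 100). The members past 4-fold were L3, S5a (Unigene154737_FOB, 8.37-fold, 2.54 to 43.4), L39 (Unigene79602_FOB, 11.5-fold, 2.83 to 101) and S14, matched to a protist (Unigene36730_FOB, 12.6-fold, 3.12 to 109.6). The heat shock list had 4 members higher, 0 lower and 31 neither (median log2 ratio 0.06, percentile 99.7), and all 4 members past 4-fold were matched outside the arthropods, heat shock protein 70 among them (Unigene156715_FOB, 6.55-fold, 4.02 to 11.3). The detoxification list had 2 members higher, 0 lower and 115 neither (median log2 ratio -0.02, percentile 100). It was led by a cytochrome P450 (Unigene12060_FOB, 4.57-fold, 3.3 to 6.44) and a microsomal glutathione S-transferase (Unigene820_FOB, 7.84-fold, 2.76 to 30.6). The mitochondrial respiration list had 2 members higher, 0 lower and 35 neither (median log2 ratio -0.02, percentile 98.5). Besides NADH dehydrogenase subunit 1, ATP synthase beta was higher (Unigene36902_FOB, 5.93-fold, 2.89 to 13.7). The chemosensation list had 0 members higher, 0 lower and 10 neither (median log2 ratio 0.40, percentile 99.8). Its members included odorant-binding protein 5 at 290 reads in the female and 161 in the male library (Unigene143110_FOB, 1.88-fold, 1.55 to 2.3).

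Inside the middle 95% of random lists were the medians of 14 lists. The cuticle and chitin list had 1 member higher, 0 lower and 47 neither (median log2 ratio -0.14, percentile 88.2). Its members included brain chitinase higher in females (Unigene157061_FOB, 6.57-fold, 2.94 to 17.3). The juvenile hormone and ecdysone list had 1 member higher, 0 lower and 50 neither (median log2 ratio -0.28, percentile 39.7). Its members included a juvenile hormone esterase higher in females (Unigene154639_FOB, 7.84-fold, 2.76 to 30.6). The egg and yolk list had 0 members higher, 1 lower and 25 neither (median log2 ratio -0.50, percentile 3.64). Its member past 4-fold was an oocyte zinc finger protein matched to a vertebrate (Unigene141887_FOB, 87-fold, 15.2 to 3474 higher in males). The digestion and sugar uptake list had 0 members higher, 2 lower and 164 neither (median log2 ratio -0.29, percentile 32.6). The transposable element list had 0 members higher, 1 lower and 79 neither (median log2 ratio -0.27, percentile 84). No member of the muscle, vision, sperm, neural signalling, immunity, protein folding, sex determination, wing patterning or embryonic patterning lists was 4-fold apart. In the same order their most abundant members were myosin regulatory light chain 2 at 1.08-fold (Unigene121008_FOB), retinoblastoma-binding protein 5 at 1.16-fold (Unigene157027_FOB), a sperm-associated antigen at 1.62-fold (Unigene137191_FOB), synapsin at 1.07-fold (Unigene153943_FOB), serpin-6 at 1.17-fold (Unigene142291_FOB), protein disulfide-isomerase A6 at 1.43-fold (Unigene152247_FOB), Sex-lethal at 1.02-fold (Unigene148793_FOB), a spalt-like protein at 1.77-fold (Unigene150934_FOB) and bicaudal D at 1.39-fold (Unigene157333_FOB). With 5 CPM added to each level in place of 1, the 1245 unigenes 4-fold apart became 259, and with at least 100 reads required they became 180.

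The same question was asked in second-instar larvae, the stage at which males secrete wax. Higher in females were a Patched-related protein (Unigene35956_FOB, 180 against 1 reads, 202-fold, 35.8 to 8015), 2 cytochromes P450 (Unigene134678_FOB, 175-fold, 30.9 to 6952, and Unigene153543_FOB, 66.9-fold, 30.4 to 184) and cytochrome P450 307a1, an enzyme of ecdysteroid synthesis that was unread in the male library (Unigene36940_FOB, at least 19.4-fold). Chitinase 7, an enzyme that breaks down old cuticle, was also higher in females (Unigene157267_FOB, 563 against 70 reads, 9.02-fold, 7.02 to 11.7). Higher in males were a small heat shock protein (Unigene142638_FOB, 2581 against 45 reads, 51.2-fold, 38.1 to 70.3), a heat shock protein 70 (Unigene45254_FOB, 1565 against 64 reads, 21.8-fold, 17 to 28.5) and a short-chain dehydrogenase/reductase (Unigene115428_FOB, 750 against 1 reads, 669-fold, 119.7 to 26455). Of 34182 unigenes measured, 1212 were at least 4-fold higher in females and 905 in males.

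Lipid enzymes were among the unigenes furthest apart. The putative elongase already higher in first-instar females was 114-fold higher here (31.3 to 951, Unigene152548_FOB). A Z9-desaturase, which places a double bond in fatty acyl chains, was higher in females (Unigene154536_FOB, 129-fold, 22.7 to 5137), and a fatty acid synthase was unread in males (Unigene35408_FOB, at least 19.4-fold). Males were higher for an AMP-dependent CoA ligase (Unigene123893_FOB, at least 43.1-fold), a firefly luciferase-like protein of the same enzyme superfamily (Unigene155797_FOB, at least 60.6-fold) and an endothelial lipase (Unigene128886_FOB, at least 41.3-fold). They were also higher for esterases: alpha-esterase 41 (Unigene103830_FOB, at least 77.3-fold), a carboxylesterase (Unigene132114_FOB, at least 54.7-fold) and a feruloyl esterase-like protein (Unigene143868_FOB, 189-fold, 33.6 to 7503). A peroxidase (Unigene107611_FOB, at least 54.1-fold) and a peroxidasin-like protein (Unigene110296_FOB, at least 52.6-fold), which belong to the haem peroxidases, stood on the same side. Females were higher for kynurenine aminotransferase, an enzyme of tryptophan breakdown (Unigene149952_FOB, 57.7-fold, 22.2 to 214), an M1 zinc metalloprotease (Unigene153638_FOB, 103-fold, 18.1 to 4118), allantoinase, an enzyme of purine breakdown (Unigene126767_FOB, at least 16.8-fold), and an Osiris protein (Unigene156895_FOB, 34.2-fold, 13 to 128).

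The cuticle and chitin list had 21 members higher, 0 lower and 21 neither (median log2 ratio 1.91, percentile 100), and brain chitinase (Unigene149758_FOB, 4.83-fold, 3.13 to 7.71), acidic chitinase (Unigene155254_FOB, 4.28-fold, 2.8 to 6.75) and chitin deacetylase 5 (Unigene86134_FOB, 7.16-fold, 4.34 to 12.5) were among the higher members. The heat shock list had 0 members higher, 6 lower and 36 neither (median log2 ratio -0.42, percentile 0), all 6 on the male side. Besides those above they included a second small heat shock protein (Unigene77751_FOB, 131-fold, 36 to 1088) and heat shock protein 70 unigenes at 8.96-fold (6.92 to 11.8, Unigene134666_FOB) and 5.31-fold (4.07 to 7.02, Unigene112925_FOB). The wax and long-chain lipid list had 8 members higher, 7 lower and 67 neither (median log2 ratio -0.29, percentile 0.11). Fatty acid synthases stood on the male side at 4.37-fold (3.30 to 5.87, Unigene47547_FOB) and 7.43-fold (5.08 to 11.2, Unigene124509_FOB), and an elongase stood on the female side (Unigene100222_FOB, 4.83-fold, 3.39 to 7.03). The juvenile hormone and ecdysone list had 1 member higher, 13 lower and 58 neither (median log2 ratio -0.25, percentile 1.25). All 13 members higher in males were juvenile hormone esterases, which break the hormone down. Examples were Unigene139627_FOB at 81.6-fold (22.3 to 679), Unigene141269_FOB at 40.1-fold (13.4 to 197), Unigene154045_FOB at 26.6-fold (12 to 73.5) and Unigene111649_FOB at 4.82-fold (2.97 to 8.20). The ribosome list had 13 members higher, 0 lower and 38 neither (median log2 ratio 0.79, percentile 100). Among them were L30 (Unigene148568_FOB, 8.6-fold, 3.66 to 24.6), L12 (Unigene13703_FOB, 10.1-fold, 3.62 to 39) and L2 (Unigene19633_FOB, 4.82-fold, 2.39 to 10.8), all matched best outside the arthropods, and acidic protein P1 (Unigene152564_FOB, 8.04-fold, 3.41 to 23.1). The neural signalling list had 0 members higher, 0 lower and 46 neither (median log2 ratio 0.71, percentile 100). Its most abundant member, a nicotinic acetylcholine receptor alpha 9 subunit, was level at 185 and 220 reads (Unigene157144_FOB, 1.06-fold, 0.868 to 1.3 in favour of males). The mitochondrial respiration list had 1 member higher, 0 lower and 35 neither (median log2 ratio -0.29, percentile 0.9), although ATP synthase beta was higher in females (Unigene36902_FOB, 7.43-fold, 3.51 to 18.1). The chemosensation list had 2 members higher, 1 lower and 6 neither (median log2 ratio 1.12, percentile 98.4). Its members included odorant-binding protein 4 higher in females (Unigene131504_FOB, 33.6-fold, 5.59 to 1372), another odorant-binding protein on the same side (Unigene33657_FOB, 5.45-fold, 2.38 to 14.6) and pheromone-degrading enzyme 2 higher in males (Unigene151747_FOB, at least 9.51-fold).

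Inside the middle 95% of random lists, the detoxification list had 12 members higher, 15 lower and 96 neither (median log2 ratio 0.09, percentile 96.5). A cytochrome P450 (Unigene12060_FOB, 21.2-fold, 12.6 to 38.3) was higher in females, and another cytochrome P450 (Unigene135553_FOB, 5.73-fold, 4.2 to 7.97) and a UDP-glucosyl transferase (Unigene146118_FOB, 5.91-fold, 4.13 to 8.69) in males. The digestion and sugar uptake list had 15 members higher, 4 lower and 150 neither (median log2 ratio 0.01, percentile 81.5). Sucrase, which splits plant sugar (Unigene156059_FOB, 22.1-fold, 11 to 52.2), aminopeptidase N (Unigene141323_FOB, 9.87-fold, 5.77 to 18.1) and a trypsin-like protease (Unigene155528_FOB, 4.21-fold, 3.02 to 5.99) were higher in females, and a pancreatic lipase-related protein in males (Unigene19105_FOB, 10.3-fold, 8.06 to 13.4). The sex determination list had 0 members higher, 2 lower and 5 neither (median log2 ratio -0.20, percentile 35.2). The 2 members were the male isoform of doublesex (Unigene155621_FOB, 18.7-fold, 4.87 to 159.7), the transcription factor that directs sexual differentiation in insects, and doublesex-Mab related 99B (Unigene36941_FOB, 15.2-fold, 3.89 to 130.3), both higher in males. The egg and yolk list had 1 member higher, 2 lower and 21 neither (median log2 ratio -0.26, percentile 7.44). PIWI, a germline small-RNA protein (Unigene150642_FOB, 12-fold, 3.03 to 104), and the oocyte zinc finger protein of vertebrate match (Unigene141887_FOB, at least 18.7-fold) were higher in males, and chorion peroxidase (Unigene49406_FOB, 6.28-fold, 2.39 to 20.8) in females. The sperm and axoneme list had 0 members higher, 4 lower and 32 neither (median log2 ratio -0.17, percentile 15.7). Of the 4 lower members, 3 were N1-acetyl-spermine/spermidine oxidases of polyamine breakdown, not sperm proteins (Unigene128947_FOB, 4.91-fold, 2.28 to 12.1, Unigene145169_FOB, 5.2-fold, 2.17 to 15.1, and Unigene82077_FOB, 5.89-fold, 2.28 to 19.3), and the other was a ciliary dynein heavy chain (Unigene35212_FOB, 9.36-fold, 2.29 to 82.4). The muscle list had 1 member higher, 1 lower and 127 neither (median log2 ratio -0.01, percentile 76.1). Its members included arginine kinase, which buffers ATP, higher in females (Unigene143238_FOB, 9.42-fold, 3.73 to 30.5) and a titin-like protein of non-arthropod match higher in males (Unigene41493_FOB, 4.91-fold, 2.28 to 12.1). The immunity list had 1 member higher, 0 lower and 41 neither (median log2 ratio -0.05, percentile 50.5). Its 1 member past 4-fold was a serpin matched outside the arthropods (Unigene153146_FOB, 5.61-fold, 2.45 to 15). The transposable element list had 1 member higher, 2 lower and 66 neither (median log2 ratio 0.15, percentile 93.5). A gag polyprotein (Unigene147556_FOB, 4.62-fold, 3.07 to 7.19) and the transposase (Unigene135148_FOB, at least 31.2-fold) were higher in males. A gag-pol polyprotein (Unigene34701_FOB, 5.38-fold, 2.01 to 18.1) was higher in females, and it and the transposase were matched outside the arthropods. No member of the cell cycle, vision, wing patterning, embryonic patterning or protein folding lists was 4-fold apart. The 2117 unigenes became 844 with a prior of 5 CPM and 441 with at least 100 reads.

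In adults, a unigene counted when each of the 3 female libraries was at least 4-fold above, or at least 4-fold below, the male library, and the ratio given is the smallest of the 3. Male adults were higher for serine protease P10, read in no other library (Unigene88618_FOB, at least 269.9-fold, 790 reads), and for a juvenile hormone esterase (Unigene57797_FOB, 423-fold, 181 to 1306). They were also higher for proteins of muscle and eye, such as myosin alkali light chain 1 (Unigene115288_FOB, at least 268-fold) and NINAC, a photoreceptor myosin needed for phototransduction (Unigene137840_FOB, at least 129-fold). Female adults were higher for a CRAL/TRIO protein, of a family that binds lipophilic ligands (Unigene155259_FOB, at least 58.8-fold), and for fatty acid synthase (Unigene151550_FOB, at least 22.7-fold). They were also higher for alpha-amylase, which digests starch (Unigene126829_FOB, 39.8-fold, 13.4 to 195), and for prophenoloxidases, the precursors of the melanising enzyme (Unigene125195_FOB, 12.6-fold, 5.94 to 32, and Unigene64640_FOB, 24.6-fold, 6.55 to 207). Of 38803 unigenes measured, 2276 were higher in females and 3105 in males, or 42.3% of calls higher in females. With library totals the counts were 2989 and 2469, or 54.8%. The median log2 ratio of all measured unigenes was 0.28, against 0.56 with library totals and 0.15 with DESeq2 size factors, so list medians are to be read against it.

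Further unigenes higher in females encoded omega (Unigene150955_FOB, at least 21-fold), ribosomal protein S9 (Unigene37030_FOB, at least 21-fold), aminopeptidase N (Unigene150745_FOB, at least 20.5-fold) and a putative fatty acid synthase (Unigene152309_FOB, at least 18.9-fold). Others encoded a luciferase-like protein (Unigene132718_FOB, at least 17.9-fold), the splicing helicase BRR2 (Unigene62872_FOB, at least 17.6-fold), venom protein 5, a name taken from its hymenopteran match (Unigene53687_FOB, at least 17.2-fold), and an ARF GTPase-activating protein of membrane traffic (Unigene156297_FOB, at least 15.3-fold). Further unigenes higher in males encoded a testis serine protease 1-like protein (Unigene114453_FOB, at least 310.2-fold) and a butyrylcholinesterase-like protein (Unigene40813_FOB, at least 174-fold), both matched outside the arthropods. Others encoded the UDP-sugar transferase Ugt86Dc (Unigene153373_FOB, at least 229.9-fold), another glucosyl transferase (Unigene144424_FOB, 167-fold, 71.3 to 517), a cytochrome P450 (Unigene105197_FOB, at least 132-fold) and myosin 2 light chain (Unigene62219_FOB, at least 97.9-fold).

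The muscle list had 0 members higher, 36 lower and 106 neither (median log2 ratio -2.02, percentile 0). Muscle-specific protein 300 (Unigene156307_FOB, 5.43-fold, 4.77 to 6.2, and Unigene155508_FOB, 5.7-fold, 4.71 to 6.95), the sarcoplasmic calcium ATPase (Unigene89387_FOB, 10.9-fold, 9.07 to 13.1) and a titin isoform (Unigene156897_FOB, 5.61-fold, 4.85 to 6.51) were among the 36. The vision list had 2 members higher, 10 lower and 32 neither (median log2 ratio -0.99, percentile 0). The lower members included 4 arrestins, which quench photoreceptor signalling, among them 3 of high level (Unigene126381_FOB, 21.3-fold, 12.9 to 37.6, Unigene22475_FOB, 29-fold, 14.4 to 67.9, and Unigene55720_FOB, 18.4-fold, 10.3 to 36.1), the rhodopsin-specific isomerase (Unigene15121_FOB, 52.7-fold, 29.1 to 106) and, chosen after its values were seen, a long-wavelength opsin (Unigene145366_FOB, 30.6-fold, 13.7 to 85). Its 2 higher members were a retinoid-inducible carboxypeptidase and a retinoblastoma-like protein, which are not eye proteins. The neural signalling list had 0 members higher, 11 lower and 37 neither (median log2 ratio -2.54, percentile 0). These included synaptotagmin-10, a vesicle release protein (Unigene156923_FOB, 7.89-fold, 5.57 to 11.5), the inebriated transporter (Unigene145697_FOB, 6-fold, 4.62 to 7.88), a calcium channel (Unigene153058_FOB, 7.78-fold, 4.95 to 12.8) and another voltage-gated channel (Unigene36922_FOB, 31.2-fold, 14 to 86.3). The mitochondrial respiration list had 0 members higher, 1 lower and 36 neither (median log2 ratio -0.73, percentile 0). NDUFV1 of complex I was its 1 member past 4-fold (Unigene82428_FOB, 4.24-fold, 3.28 to 5.53). The transposable element list had 1 member higher, 12 lower and 68 neither (median log2 ratio -0.49, percentile 0). Its members included gag-pol polyproteins of non-arthropod match at 32.8-fold (17.5 to 69.2, Unigene110908_FOB), 5.89-fold (4.19 to 8.45, Unigene152169_FOB) and 8.37-fold (4.58 to 16.8, Unigene34701_FOB) and another gag-pol protein (Unigene34423_FOB, 5.64-fold, 3.26 to 10.3) on the male side.

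The wax and long-chain lipid list had 32 members higher, 12 lower and 55 neither (median log2 ratio 2.24, percentile 100). Another fatty acid synthase was higher in females (Unigene155599_FOB, 16.1-fold, 6.07 to 60.4), and 2 long-chain fatty acid CoA ligases, which activate fatty acids, were higher in males (Unigene119148_FOB, 14.8-fold, 11 to 20.3, and Unigene81319_FOB, 15.5-fold, 11.6 to 21.3). The ribosome list had 19 members higher, 0 lower and 27 neither (median log2 ratio 2.36, percentile 100). It was led by L37 (Unigene12684_FOB, 8.65-fold, 6.46 to 11.8), S19a (Unigene133260_FOB, 6.61-fold, 4.7 to 9.55), L3 (Unigene106617_FOB, 4.36-fold, 3.11 to 6.25) and L11e (Unigene74293_FOB, 5.79-fold, 3.84 to 9.07). The cell cycle list had 16 members higher, 0 lower and 68 neither (median log2 ratio 1.48, percentile 100). It was led by MCM7 (Unigene156125_FOB, 13.1-fold, 6.73 to 29.2), PCNA, the replication clamp (Unigene145687_FOB, 5.12-fold, 3.15 to 8.73), cyclin B (Unigene148260_FOB, 33.3-fold, 5.68 to 1342) and cyclin B3 (Unigene156677_FOB, 20.3-fold, 5.35 to 171). The immunity list had 12 members higher, 1 lower and 38 neither (median log2 ratio 1.53, percentile 100). Its higher members included pro-phenoloxidase 2 (Unigene142720_FOB, 4.79-fold, 3.23 to 7.34) and prophenoloxidase (Unigene3628_FOB, 13.7-fold, 2.18 to 571). The detoxification list had 19 members higher, 15 lower and 132 neither (median log2 ratio 1.17, percentile 100). A UDP-glucuronosyltransferase (Unigene149933_FOB, 8.52-fold, 4.32 to 19.1) and a cytochrome P450 of the 4V type and non-arthropod match (Unigene147251_FOB, at least 3.62-fold) were higher in females, and a cytochrome P450 was higher in males (Unigene145761_FOB, 17-fold, 11.9 to 25). The protein folding list had 5 members higher, 1 lower and 38 neither (median log2 ratio 1.53, percentile 100). These included a translocon-associated protein (Unigene133787_FOB, 5.68-fold, 4.06 to 8.14), Sec61 alpha, the channel into the endoplasmic reticulum (Unigene137588_FOB, 6.93-fold, 3.82 to 13.8, and Unigene124479_FOB, 7.17-fold, 3.85 to 14.8), and coatomer alpha (Unigene150727_FOB, 5.06-fold, 2.82 to 9.87). The egg and yolk list had 1 member higher, 0 lower and 40 neither (median log2 ratio 1.79, percentile 100), chorion peroxidase being its 1 member past 4-fold (Unigene58303_FOB, 5.41-fold, 1.87 to 21.4). With unread members at the floor of 3 reads, the medians were 1.84 (wax), 1.45 (ribosome), 1.60 (egg and yolk), 1.51 (immunity), 1.13 (detoxification) and 1.5 (protein folding).

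Inside the middle 95% of random lists were 9 lists. The juvenile hormone and ecdysone list had 6 members higher, 5 lower and 61 neither (median log2 ratio 0.57, percentile 71.9). Its members included juvenile hormone esterases higher in males (Unigene61508_FOB, 161-fold, 68.6 to 497, and Unigene154045_FOB, 5.2-fold, 3.86 to 7.12) and in females (Unigene128712_FOB, 21-fold, 5.55 to 177). The digestion and sugar uptake list had 20 members higher, 14 lower and 151 neither (median log2 ratio 0.51, percentile 72). Sucrase (Unigene156059_FOB, 15.9-fold, 4.15 to 136) and cathepsin B1, of non-arthropod match (Unigene70250_FOB, at least 12.1-fold), were higher in females and a sugar transporter in males (Unigene147730_FOB, 6.92-fold, 5.2 to 9.35). With unread members at the floor its median was 0.54. The cuticle and chitin list had 1 member higher, 5 lower and 45 neither (median log2 ratio 0.84, percentile 91.9). Its members included cuticular protein 111 (Unigene146049_FOB, 11.9-fold, 9.42 to 15.2), pupal cuticle protein Edg-78E (Unigene54197_FOB, 4.47-fold, 3.02 to 6.78) and another cuticular protein (Unigene80939_FOB, 14.2-fold, 8.2 to 26.7) higher in males and a protist-matched chitinase in females (Unigene79529_FOB, 12.3-fold, 3.15 to 106). At the floor its median was 0.86. The heat shock list had 3 members higher, 7 lower and 31 neither (median log2 ratio 0.81, percentile 91.7). Heat shock protein 70 unigenes were higher in males at 14.5-fold (11 to 19.4, Unigene134666_FOB), 11.1-fold (8.22 to 15.3, Unigene112925_FOB) and 11.4-fold (8.02 to 16.7, Unigene122371_FOB), and a mitochondrial one of non-arthropod match in females (Unigene91592_FOB, 4.49-fold, 3.04 to 6.83). At the floor its median was 0.91. The chemosensation list had 1 member higher, 4 lower and 9 neither (median log2 ratio -0.40, percentile 7.6). Its members included an olfactory receptor (Unigene25454_FOB, at least 13.7-fold), gustatory receptor 43a (Unigene31049_FOB, at least 11.9-fold) and odorant receptor Or7 (Unigene100557_FOB, at least 9.91-fold) higher in males and pheromone-degrading enzyme 2 in females (Unigene139104_FOB, 13.7-fold, 2.18 to 571). The sex determination list had 0 members higher, 1 lower and 5 neither (median log2 ratio -0.66, percentile 5.39). Its 1 member past 4-fold was the male isoform of doublesex (Unigene155621_FOB, at least 7.52-fold). The wing patterning list had 1 member higher, 1 lower and 10 neither (median log2 ratio -0.13, percentile 15.4). Vestigial, a selector of wing identity (Unigene156679_FOB, 5.09-fold, 3.03 to 8.96), was higher in males and apterous (Unigene121839_FOB, 8.32-fold, 2.06 to 72.8) in females. The sperm and axoneme list had 1 member higher, 1 lower and 33 neither (median log2 ratio 0.95, percentile 96.6). Spermidine synthase, a polyamine enzyme, was higher in females (Unigene83842_FOB, 7.88-fold, 4.13 to 16.9) and the testis serine protease in males. The embryonic patterning list had 0 members higher, 0 lower and 13 neither (median log2 ratio 1.26, percentile 86.1), or a median of 0.84 at the floor.

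The 3 adult ratios shared the male library. With unchanged genes and counting error alone, simulation gave on average 0.4 unigenes apart in all 3, and with the median spread of the test across stages it gave 670, of which 561 were higher in females. Independent lists of the same sizes would share 220, against the 5381 observed, so part of the excess may come from the shared male library. Leaving out the early adult library raised the count from 5381 to 8583, of which 5269 were also in the first set. Of the calls, 1698 had a library at 0 reads, and 1378 of these were still 4-fold apart with 3 reads in its place.

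**Figure D1:**
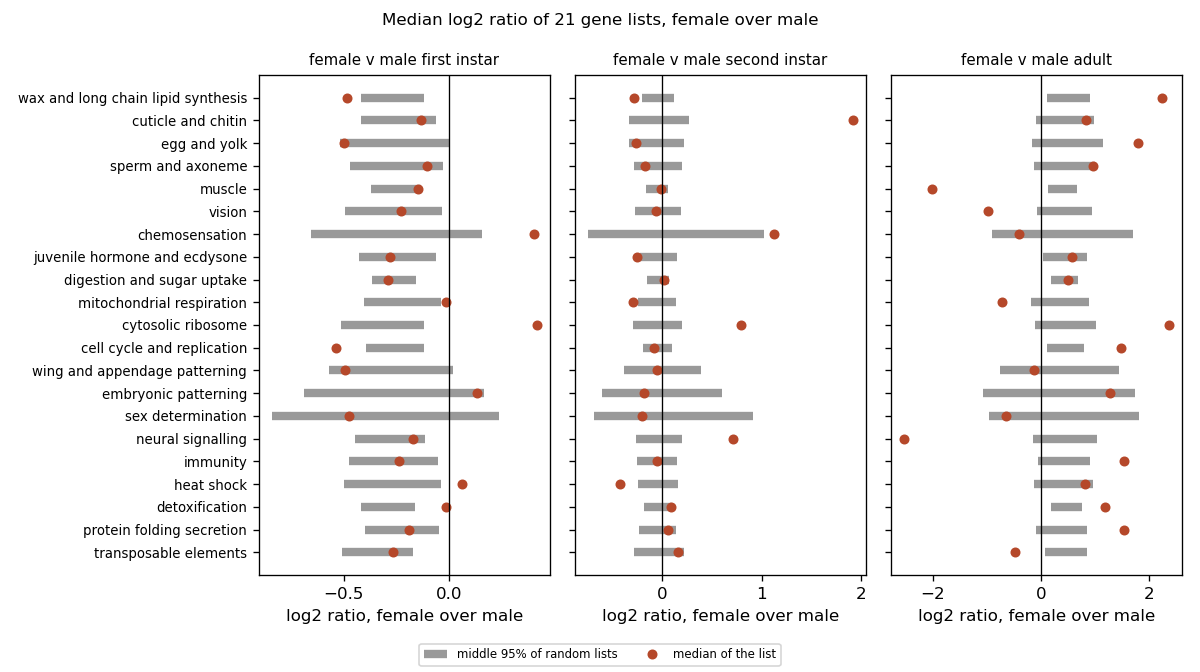
Median log2 ratio, female over male, of the members of 21 gene lists (points) in first-instar, second-instar and adult insects, with the middle 95% of 10000 random lists matched on expression (grey bars). The horizontal axes differ in range between panels. In adults the muscle and neural signalling medians, at -2.02 and -2.54, lie furthest below the bars.

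**Figure D2:**
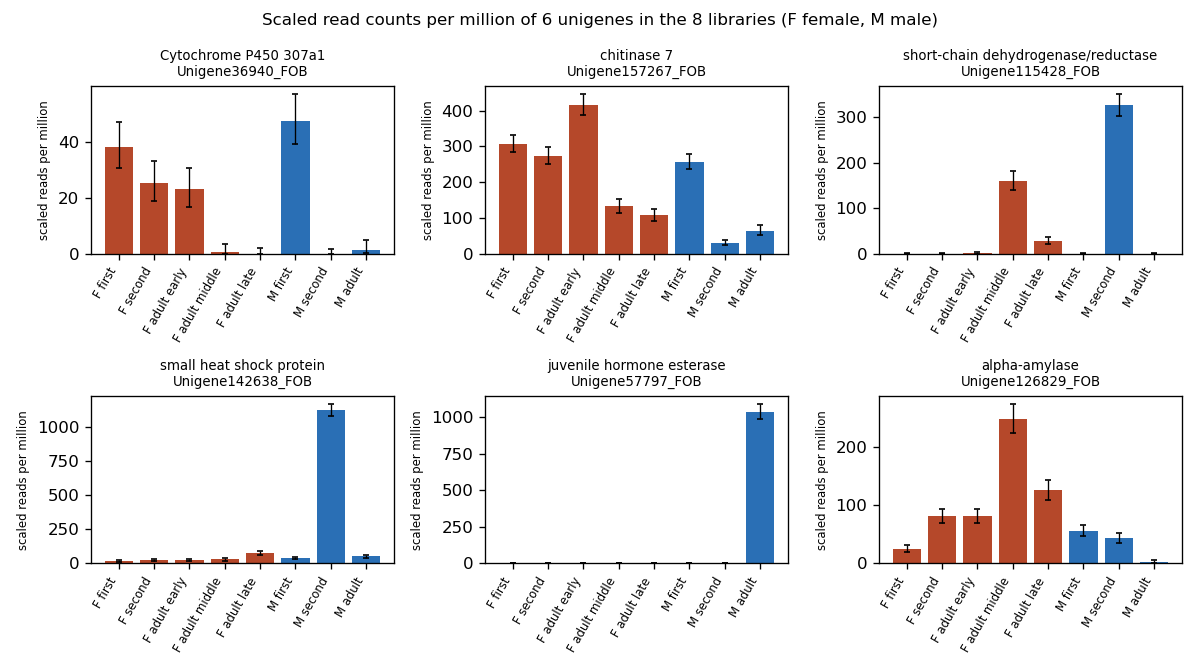
Scaled CPM (vertical axis, linear, from 0) of 6 unigenes in the 8 libraries, female in red and male in blue, with exact 95% counting intervals as error bars. Juvenile hormone esterase Unigene57797_FOB reaches 1038 CPM in male adults and 2.45 or less in the other 7 libraries, and the small heat shock protein Unigene142638_FOB reaches 1122 in male second instars.

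Overlap between the larval sex differences was larger than that of unrelated lists. Of 30075 unigenes measured in both instars, 115 were higher in females in both, against 16.2 for independent lists, and 63 were higher in males in both, against 1.09. The putative elongase Unigene152548_FOB and ATP synthase beta (Unigene36902_FOB) were higher in females in both, and the zinc finger protein Unigene138890_FOB, the oocyte zinc finger protein Unigene141887_FOB and the transposase Unigene135148_FOB were higher in males in both. These comparisons shared no library. Across unigenes the log2 ratios of the 2 instars had a Pearson correlation of 0.187, and unigenes are not independent replicates. With a 2-fold rule the shared count rose from 178 to 1027, and with at least 100 reads it was 31.

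A test across all 8 libraries asked for a sex difference common to the stages. The unigenes with the lowest adjusted p higher in males were the Tigger element Unigene144418_FOB (log2 -7.32, SE 0.716, adjusted p = 0.201, edgeR quasi-likelihood test), the zinc finger protein Unigene138890_FOB (log2 -7.51, SE 0.792, adjusted p = 0.209) and an NAD-dependent methanol dehydrogenase (Unigene142428_FOB, log2 -2.87, SE 0.462, adjusted p = 0.745). Higher in females was a zinc finger protein matched to a mammal (Unigene140794_FOB, log2 3.71, SE 0.499, adjusted p = 0.332), with 59 to 89 reads in the 5 female and 2 to 13 in the 3 male libraries. The male isoform of doublesex had a log2 ratio of -4.53 (SE 0.938, adjusted p = 0.890, Unigene155621_FOB), with 0 to 4 reads in the female and 16 to 42 in the male libraries. Others named by the rule, each with adjusted p = 0.890 by edgeR, were on the female side a knottin antimicrobial peptide (log2 3.05, Unigene144467_FOB), a sodium/phosphate cotransporter (log2 5.36, Unigene135900_FOB), sucrase (log2 5.64, Unigene156059_FOB) and ribosomal proteins L7a, of vertebrate match (log2 2.63, Unigene155941_FOB) and L39 (log2 3.43, Unigene79602_FOB). They also included zinc finger 717-like, of mammalian match (log2 1.52, Unigene127152_FOB), a pyridoxamine phosphate oxidase (log2 4.65, Unigene143374_FOB), furrowed (log2 1.67, Unigene142936_FOB) and an ammonium transporter (log2 2.32, Unigene151807_FOB). On the male side they were the transposase (log2 -8.67, Unigene135148_FOB), UDP-glucuronosyltransferase 2A3 (log2 -2.26, Unigene139880_FOB), a small heat shock protein (log2 -4.00, Unigene77751_FOB), the titin-like protein (log2 -1.84, Unigene41493_FOB), sialin (log2 -1.89, Unigene120592_FOB) and a phosphate cotransporter (log2 -2.42, Unigene153568_FOB). No unigene of 51155 passed the edgeR quasi-likelihood test at an adjusted p of 0.05, and 2339 had an unadjusted p below that value. DESeq2 called 90 (47 higher in females, 43 in males). Some were high in 1 library, such as Unigene106353_FOB (2316 reads in late adult females, at most 14 elsewhere).

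With camera at a preset correlation, 13 of 21 lists had an adjusted p below 0.05, and none did with an estimated correlation, where the lowest was adjusted p = 0.244. Higher in females were the ribosome (71 members, adjusted p = 1.94e-22, and adjusted p = 0.244 with an estimated correlation), protein folding (46, p = 2.28e-04, and 0.686), detoxification (179, p = 4.88e-04, and 0.685), cell cycle (114, p = 5.01e-04, and 0.686), wax and long-chain lipid (105, p = 0.00137, and 0.686), cuticle and chitin (53, p = 0.00356, and 0.686) and immunity (55, p = 0.0224, and 0.686) lists. Higher in males were the muscle (143 members, adjusted p = 3.76e-20, and adjusted p = 0.685 with an estimated correlation), neural signalling (84, p = 2.78e-06, and 0.686), mitochondrial respiration (38, p = 2.78e-06, and 0.686), sex determination (14, p = 0.00178, and 0.244), transposable element (172, p = 0.0227, and 0.685) and vision (54, p = 0.0288, and 0.685) lists. The other 8 lists had adjusted p from 0.135 for egg and yolk to 0.723 for juvenile hormone and ecdysone. For the latter camera gave a male direction while the median and mean log2 ratios were 0.03 and 0.07, and for embryonic patterning the median was -0.08 and the mean 0.01. Adjusted over the list alone, 1 unigene passed the edgeR test in the sex determination list, the male isoform of doublesex, and 0 passed in each of the other 20 lists. The list calls rested in large part on the male adult library. Without it 7 lists had an adjusted p below 0.05 with camera. Of the 13 lists called with all libraries 5 then turned direction with camera: wax (adjusted p = 0.00947), cell cycle (adjusted p = 2.53e-04), immunity (adjusted p = 0.483) and protein folding (adjusted p = 0.888) to male, and neural signalling to female (adjusted p = 0.0394). The egg and yolk list was called by camera in the male direction (adjusted p = 0.0191). Muscle, mitochondrial respiration and detoxification (adjusted p = 0.393 each) and vision and transposable elements (adjusted p = 0.952 each) were no longer called by camera. Without either second-instar library the cuticle list was no longer called (adjusted p = 0.938 by camera in both cases). Sex determination was not called by camera without any 1 of the 4 larval libraries (adjusted p from 0.101 to 0.223), transposable elements without either first-instar or the early adult female library (adjusted p from 0.0564 to 0.202), and immunity without the middle adult female library (adjusted p = 0.0731). Egg and yolk was called by camera in the female direction without any 1 larval or the early adult female library (adjusted p from 0.00223 to 0.0320), digestion without the female (adjusted p = 0.0388) or male first-instar library (adjusted p = 0.0373), and chemosensation without late adult females (adjusted p = 0.0436).

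The remaining comparisons followed development within each sex, and percentiles refer to the same kind of random lists. Other lists outside the middle 95% are given by their median log2 ratio alone. From first to second instar in females, sucrase was higher in the second instar, at 158 against 8 reads (Unigene156059_FOB, 22.6-fold, 11.2 to 53.3). Prolyl 4-hydroxylase alpha-1, a collagen-modifying enzyme (Unigene118681_FOB, at least 8.78-fold), and a fatty acyl-CoA elongase (Unigene147440_FOB, 12.9-fold, 5.99 to 33.2) were higher in the same library. Higher in the first instar were a cytochrome P450 (Unigene156686_FOB, 337 against 18 reads, 16.4-fold, 10.2 to 27.9), fibroinase, a cathepsin-type protease (Unigene151513_FOB, 109 against 4 reads, 23.8-fold, 9.04 to 88.9), and the histidine-rich glycoprotein precursor matched outside the arthropods (Unigene118576_FOB, at least 11.4-fold). Of 34172 unigenes, 373 were higher in the second instar and 475 in the first. The muscle list had 10 members higher, 0 lower and 110 neither (median log2 ratio 1.03, percentile 100). The immunity list had 4 members higher, 0 lower and 37 neither (median log2 ratio 0.44, percentile 99.8). The chemosensation list had 0 members higher, 2 lower and 8 neither (median log2 ratio -0.82, percentile 0.01). The heat shock list had 0 members higher, 0 lower and 37 neither (median log2 ratio 0.62, percentile 100). Outside were 12 of 21 lists, 6 above and 6 below, further ones being juvenile hormone (0.36), digestion (0.31) and cell cycle (0.29) above, and respiration (-0.10), wing patterning (-0.23), embryonic patterning (-0.35), neural (-0.20) and transposable elements (-0.08) below. The 848 unigenes became 197 with a prior of 5 CPM and 162 with at least 100 reads.

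Early adult females differed least from second-instar females. A serpin, a protease inhibitor (Unigene152574_FOB, 180 against 7 reads, 25.9-fold, 12.3 to 65.3), and the cytochrome P450 that was low in the second instar (Unigene156686_FOB, 327 against 18 reads, 18.3-fold, 11.4 to 31.2) were higher in early adults, as was a pG1 protein of non-arthropod match (Unigene35606_FOB, at least 14.4-fold). Aminopeptidase N was higher in the second instar (Unigene32210_FOB, 145 against 34 reads, 4.24-fold, 2.9 to 6.35), with 2 protist-matched unigenes, a lipoprotein (Unigene156558_FOB, at least 13.3-fold) and RNA polymerase II subunit RPB1 (Unigene36050_FOB, 5.57-fold, 2.12 to 18.5). Of 31975 unigenes, 413 were higher in early adults and 33 in the second instar. The cuticle list had 2 members higher, 0 lower and 44 neither (median log2 ratio 0.51, percentile 100). The ribosome list had 0 members higher, 0 lower and 53 neither (median log2 ratio -0.49, percentile 0). Outside were 6 of 21 lists, 2 above and 4 below, further ones being detoxification (0.20) above, and muscle (-0.21), cell cycle (-0.35) and neural (-0.28) below. The 446 unigenes became 188 with a prior of 5 CPM and 128 with at least 100 reads.

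Among adult females, HR3, an ecdysone-induced nuclear receptor (Unigene149930_FOB, 200 against 0 reads, at least 49.4-fold), the Patched-related protein (Unigene35956_FOB, 396 against 1 reads, 294-fold, 52.4 to 11625) and the cytochrome P450 Unigene156686_FOB (242-fold, 43.2 to 9605) were higher in the early than in the middle stage. Esterase E4, of hymenopteran best match (Unigene154182_FOB, 330 against 0 reads, at least 148-fold), a prophenoloxidase (Unigene153675_FOB, 322 against 0 reads, at least 145-fold) and the luciferase-like protein (Unigene155797_FOB, 135 against 0 reads, at least 60.7-fold) were higher in the middle stage. Of 30917 unigenes, 833 were higher in the middle and 2358 in the early stage. The cuticle list had 1 member higher, 13 lower and 33 neither (median log2 ratio -1.33, percentile 0). In the same order neural signalling had 0, 14 and 20 (-1.82, percentile 0). Muscle had 0, 7 and 111 (-0.84, percentile 0) and immunity 9, 3 and 35 (0.94, percentile 100). Outside were 7 of 20 lists, 4 above and 3 below, further ones being egg and yolk (0.50), ribosome (0.28) and detoxification (0.47) above. The ribosome median was 1.16 for hymenopteran (percentile 100) and -1.33 for non-arthropod matches (0.34). Hemipteran (0.42) and other arthropod matches (-0.25) lay inside the random range. The 3191 became 1457 with a prior of 5 CPM and 638 with at least 100 reads.

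Late adult females were higher than middle ones for 2 ectonucleotide pyrophosphatases (Unigene55404_FOB, 305 against 0 reads, at least 90.1-fold, and Unigene113281_FOB, 398 against 1 reads, 353-fold, 63 to 13972) and for a 46 kDa salivary protein (Unigene133780_FOB, 645 against 2 reads, 286-fold, 78.8 to 2366). The serine protease inhibitor-like protein (Unigene117056_FOB, 797 against 15 reads, 59.9-fold, 36.1 to 108), a fatty acid synthase (Unigene150673_FOB, 76 against 0 reads, at least 28.6-fold) and a UDP-glucuronosyl transferase (Unigene151995_FOB, 73 against 0 reads, at least 27.4-fold) were higher in the middle stage. Of 27850 unigenes, 1252 were higher in the late and 1079 in the middle stage. The egg and yolk list had 15 members higher, 0 lower and 24 neither (median log2 ratio 1.26, percentile 100). The embryonic patterning list had 6 members higher, 0 lower and 4 neither (median log2 ratio 3.17, percentile 100), or 2.78 with unread members at 3 reads. All 6 but hunchback (21 against 1 reads) were bicaudal C unigenes also counted in the egg list. In the same order immunity had 2, 7 and 35 (-0.49, percentile 0) and detoxification 11, 19 and 93 (-0.36, percentile 0). Outside were 14 of 20 lists, 4 above and 10 below, further ones being cell cycle (0.63) and protein folding (0.62) above, and wax (-0.29), cuticle (-0.42), muscle (-0.16), vision (0.02), chemosensation (-1.05), digestion (0.01), respiration (0.06) and neural (-0.07) below. The median of all unigenes was 0.28, against 0.11 with library totals and 0.15 with DESeq2 size factors. The 2331 became 1226 with a prior of 5 CPM and 497 with at least 100 reads.

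In males, the second instar was higher than the first for the short-chain dehydrogenase/reductase (Unigene115428_FOB, 750 against 1 reads, 801-fold, 143 to 31671), the feruloyl esterase-like protein (Unigene143868_FOB, at least 75.5-fold) and the luciferase-like protein (Unigene155797_FOB, at least 72.6-fold). The first instar was higher for fibroinase (Unigene151513_FOB, 871 against 1 reads, 816-fold, 146 to 32257), a cathepsin L-like protease (Unigene121322_FOB, 432 against 1 reads, 405-fold, 72.2 to 16017) and the Patched-related protein (Unigene35956_FOB, 274 against 1 reads, 257-fold, 45.7 to 10173). Of 36667 unigenes, 1455 were higher in the second and 1510 in the first instar. The cuticle list had 0 members higher, 23 lower and 24 neither (median log2 ratio -2, percentile 0). In the same order neural signalling had 0, 9 and 58 (-1.15, percentile 0). Heat shock had 14, 0 and 24 (1.01, percentile 100) and juvenile hormone and ecdysone 17, 2 and 55 (0.34, percentile 100). Outside were 7 of 21 lists, 4 above and 3 below, further ones being muscle (0.91) and immunity (0.39) above, and wing patterning (-0.77) below. The 2965 became 1006 with a prior of 5 CPM and 591 with at least 100 reads.

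Adult males were higher than second-instar males for juvenile hormone esterase (Unigene57797_FOB, 1531 against 1 reads, 2388-fold, 428 to 94373), serine protease P10 (Unigene88618_FOB, at least 411-fold) and the testis serine protease of non-arthropod match (Unigene114453_FOB, at least 418-fold). The second instar was higher for the short-chain dehydrogenase/reductase (Unigene115428_FOB, 750 against 0 reads, at least 160.3-fold) and for 2 CRAL/TRIO proteins (Unigene133642_FOB, at least 83.4-fold, and Unigene125511_FOB, at least 71.2-fold). Of 35017 unigenes, 4450 were higher in adults and 4612 in the second instar, so that 49.1% of calls were higher in adults. With library totals the counts were 3533 and 6101, or 36.7% higher in adults. The median of all unigenes was -0.27, against -0.63 with library totals and -0.07 with DESeq2 size factors. The wax and long-chain lipid list had 14 members higher, 56 lower and 13 neither (median log2 ratio -3.41, percentile 0), or a median of -2.94 with unread members at 3 reads, and the muscle list had 44 members higher, 0 lower and 100 neither (median log2 ratio 1.25, percentile 100). The vision list had 12 members higher, 5 lower and 28 neither (median log2 ratio 0.82, percentile 100). The chemosensation list had 5 members higher, 2 lower and 4 neither (median log2 ratio 1.64, percentile 100). The cell cycle list had 2 members higher, 30 lower and 54 neither (median log2 ratio -1.57, percentile 0) and the ribosome list 1 member higher, 16 lower and 15 neither (median log2 ratio -1.93, percentile 0). Outside were 14 of 21 lists, 7 above and 7 below, further ones being cuticle (1.29), digestion (-0.28), neural (1.46) and transposable elements (0.55) above, and egg and yolk (-1.35), immunity (-1.50), heat shock (-1.10) and protein folding (-1.33) below. The 9062 became 4644 with a prior of 5 CPM and 2610 with at least 100 reads.

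**Figure D3:**
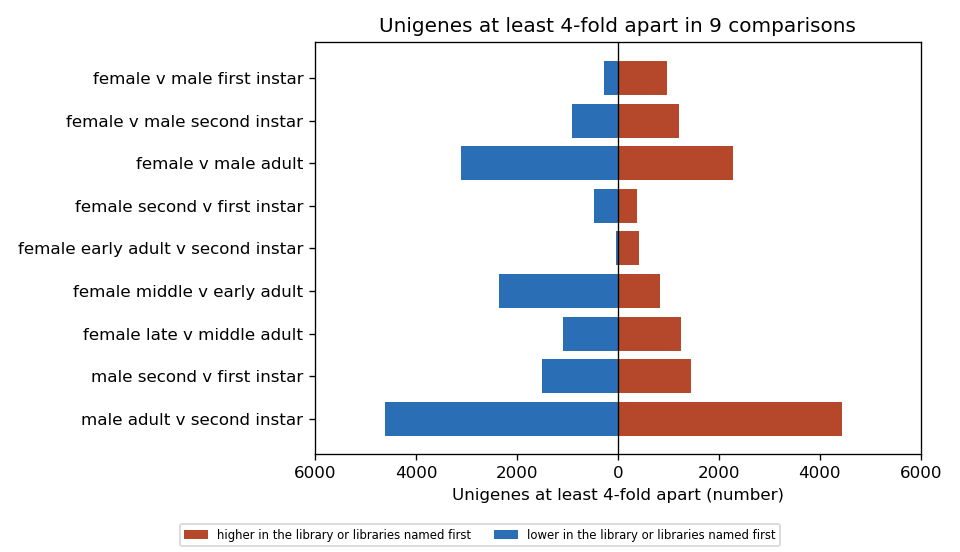
Number of unigenes at least 4-fold apart in each of 9 comparisons (horizontal axis, linear), higher in the library or libraries named first to the right (red) and lower to the left (blue). The adult male and second-instar male libraries differ in the most unigenes, 4450 and 4612, and the early adult and second-instar female libraries in the fewest, 413 and 33.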

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

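The results here are list medians and unigene ratios of opposite sign in different stages. The differences between stages were not themselves tested, since each stage has 1 library per sex in larvae and 1 male library in adults. Only the values for arthropod matches alone were chosen after the result was seen. The median log2 ratio of all annotated unigenes was -0.26 in the first instar, -0.05 in the second and 0.44 in adults, and in both larval stages most members of these lists were not 4-fold apart. The wax and long-chain lipid list had medians of -0.48 in first-instar larvae (3 members higher in females, 5 lower and 68 neither), -0.29 in the second instar (8, 7 and 67) and 2.24 in adults (32, 12 and 55), or 1.84 with unread members at 3 reads. The cell cycle list had a median of -0.54 in the first instar (0 higher, 0 lower and 88 neither) and 1.48 in adults (16, 0 and 68). With arthropod matches alone the first-instar median was -0.39, at percentile 6.3 of random lists, inside their middle 95%. The neural signalling list had a median of 0.71 in the second instar, with 0 higher, 0 lower and 46 neither, and of -2.54 in adults (0, 11 and 37). The heat shock list had medians of 0.06 in the first instar (4, 0 and 31) and -0.42 in the second (0, 6 and 36). All 4 were matched outside the arthropods, and with arthropod matches alone the first instar had 0 members past 4-fold and a median of 0.04, at percentile 98.8.

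Of the unigenes measured in both stages of a pair, 23 were 4-fold apart in opposite directions between the first and second instar, against 8.40 for independent lists, 58 between the first instar and adults, and 84 between the second instar and adults. Mitogen-activated protein kinase kinase kinase 15 was lower in female larvae (log2 -4.33 in the first and -4.91 in the second instar) and higher in female adults (2.04, Unigene144260_FOB). The ASK family kinase, matched outside the arthropods, went the same way (-4.08, -3.53 and 2.78, Unigene149053_FOB). Between second-instar larvae and adults, arginine kinase went from 2.76 to -4.71 (Unigene143238_FOB), kynurenine aminotransferase from 5.21 to -2.84 (Unigene149952_FOB), pupal cuticle protein Edg-78E from 3.97 to -2.10 (Unigene54197_FOB) and a gag-pol polyprotein of non-arthropod match from 2 to -2.92 (Unigene34701_FOB).

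By edgeR the test across stages called 0 unigenes. All 56 splits of the 8 libraries into 5 and 3 reach 0, so other splits decide nothing here. Of the other splits 3 gave 4288 each, and the rest gave 0. In each of the 3, both larvae of a stage were on the same side and the 3 female adults were opposite the male adult, so that with stage in the design only the adults were compared. Their calls could reflect the 1 male adult library.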

How the results depend on the processing

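Here leaving out unigenes matched outside the arthropods, or single female adult libraries, was chosen after the data were seen. Counts of unigenes 4-fold apart stayed within 1.5 times under both other scalings, a prior of 0.1 CPM and thinning. They did so without matches outside the arthropods, unmatched unigenes being kept. A counting interval that excludes 1 tests little, as nearly all 4-fold calls already met it. Counts moved with the added amount and the read minimum, which set how many low unigenes are counted. With 5 CPM added, in the order of the sex comparisons, female steps and male steps above, they were 259, 844, 2602, 197, 188, 1457, 1226, 1006 and 4644. With at least 100 reads they were 180, 441, 2044, 162, 128, 638, 497, 591 and 2610. With no minimum they were 2541, 3822, 7036, 1642, 944, 6839, 5395, 5017 and 14314, of which the adult count was within 1.5 times. The adult count ranged from 5773 to 8583 when 1 female library was left out, the highest without the early one. Fewer libraries then had to pass, so a rise was largely built in.

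The test across stages called 0 unigenes by edgeR with either other scaling, summed female adults, thinned counts and each library left out, and by limma-voom. It called 90 by DESeq2, 646 with no filter, 16 without the stage term and 3 by limma-trend, and the cause was not tested. In place of 13 called lists there were 0 with an estimated correlation, 1 with fry (sex determination), and 7 to 14 with a library left out. Leaving out libraries turned the camera direction of 6 of the 13 called lists at least once, and of uncalled ones such as egg and yolk. The adjusted p of the 6 ranged from 1.88e-05 to 0.00947 for wax, 4.88e-08 to 0.0199 for cell cycle, 6.64e-11 to 0.0394 for neural signalling, 0.00265 to 0.483 for immunity, 1.46e-05 to 0.888 for protein folding, and 3.10e-06 to 0.938 for cuticle, the last without either second-instar library and the others without male adults. The larval overlap was 178 unigenes, 183 with library totals, 1027 with a 2-fold rule and 31 with at least 100 reads. Of the 63 list medians in the sex comparisons, 27 lay outside the middle 95% of random lists. All 63 stayed inside or outside with a prior of 0.1. They also did with library totals, but scaling shifts a list and its random lists alike, so this tests little. With at least 100 reads 11 of 47 moved in or out, and mitochondrial respiration in the first instar turned from -0.02 to 0.0639. With arthropod matches alone 3 of 63 moved in or out. Of 1200 values of named unigenes under alternatives, 76 fell below 4-fold, 59 of them with 5 CPM added, and 0 changed direction. A change of direction was scored only for unigenes already past 4-fold. These alternatives could hardly turn such ratios, so the absence of reversals tests little. Unigenes near 20 reads are limited by depth: a ratio against 1 to 3 reads has an interval that spans more than an order of magnitude.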

Other observations

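In this part all tests were chosen after the results were seen. Genes in the first 2 paragraphs were also chosen after their values were seen. Of 39 egg list members measured in late and middle adult females, 15 were higher in late ones and 24 were not 4-fold apart. The 15 carried 2 gene names, and whether they are pieces of 2 genes was not tested. Of them 10 were unigenes of the vitellogenin receptor, which takes yolk protein into the oocyte. Examples were Unigene157486_FOB, 50.7-fold, 32.3 to 84.6, with 1087 reads against 19, Unigene148888_FOB, 35.9-fold, 19.9 to 72.5, and Unigene141185_FOB, 77.7-fold, 26.3 to 379. The other 5 matched bicaudal C, an RNA-binding protein of the oocyte, such as Unigene137997_FOB, 121-fold, 21.4 to 4832 and Unigene149453_FOB, 21.8-fold, 9.1 to 68.4. Unigene157486_FOB had 1 to 14 reads in males and 1 or 2 in female larvae and early adults.

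A set of 87 unigenes had at least 20 reads in female first and second instars, female early adults and male first instars and at most 3 in each of the other 4 libraries. Among them were cytochrome P450 307a1 (Unigene36940_FOB), cuticular protein 70 (Unigene147188_FOB), cuticular protein CPG15B (Unigene35482_FOB), odorant-binding protein 4 (Unigene131504_FOB), 2 p270 unigenes (Unigene155339_FOB and Unigene28497_FOB) and allantoinase (Unigene126767_FOB). Another 25 unigenes had at least 20 reads in female middle and late adults and male second instars alone, the highest count for any 3 libraries. They included the short-chain dehydrogenase/reductase (Unigene115428_FOB), the luciferase-like protein (Unigene155797_FOB), a sugar transporter (Unigene155611_FOB), glucose dehydrogenase (Unigene152876_FOB) and beta-galactosidase (Unigene81078_FOB).

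Ribosomal protein unigenes were higher in female than in male larvae, with median log2 ratios for best matches outside the arthropods of 1.35 in the first and 1.86 in the second instar, against 1.28 and 1.16 for arthropods that were neither hemipteran nor hymenopteran, 0.20 and 0.76 for hymenopteran and 0.27 and 0.63 for hemipteran matches. The smaller difference between the first and the last set was 1.08, which RNA of another eukaryote in the female larval libraries could produce, although other arthropod matches were nearly as high in the first instar. The summed level of the non-arthropod set was 257, 299 and 235 CPM in female larvae and early adults and 93.3 CPM or less in the other 5 libraries, and a cobalamin-independent methionine synthase, an enzyme that animals lack, followed it (31, 41 and 50 reads, and 10 or fewer elsewhere, Unigene155215_FOB). The insect's own genes may also differ, as the hemipteran-matched members lay at percentile 99.87 of random lists in the first and 99.96 in the second instar, but their summed level was 771 CPM in females against 767 in males in the first and 957 against 554 in the second, and neither explanation is excluded. Of the 976 unigenes higher in first-instar females 82 had a match, 25 of them (30.5%) outside the arthropods, against 7.84% of 18116 matched unigenes that were not 4-fold apart, and the origin of the unmatched ones was not tested.

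Unigenes nearly confined to the middle adult female library, with at least 80% of their scaled reads there, had hymenopteran best matches in 36 of 58 cases, or 62.1% (exact 95% interval 48.4% to 74.5%). The share was 24.6% of all matched unigenes and 24.8% at most in another library. RNA of a hymenopteran, such as a parasitoid, in that library is a candidate explanation. Against a change in the insect's own genes stood 16 ribosomal protein unigenes among the 58, 15 of them of hymenopteran match, where no other library had more than 2, which a regulated change in 1 insect would not be likely to add. Which further unigenes of that library belong to another insect was not tested.

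In the 3 male libraries 17 unigenes had at least 20 reads each and at most 3 in every female library, among them the transposase, the zinc finger protein and the Tigger element. No unigene had the reverse pattern at 20 reads. Chance combination of libraries is argued against, as 1 of the 55 other sets of 3 libraries had as many. Sequence differences between the insects sampled as females and as males could give unigenes restricted to either sex, and at 10 reads 11 were restricted to females against 28 to males, so that explanation stays open. A male-limited or a male-expressed sequence would give the same counts and was not tested.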
